A study of Drosophila melanogaster with 2 samples.

How the data were processed

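Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was performed on whole Drosophila melanogaster embryos collected 0 to 18 hours after egg laying, per the labels. The flies carried a transgene for a fusion of Dip2 with enhanced green fluorescent protein, and the fusion protein was precipitated with an antibody against GFP, per the labels' description. The labels name 2 biological replicates of this 1 group, chromatin sheared by sonication to 200 to 800 bp, and the assembly dm6. The antibody field names Dip2 and the source field names the targeted gene Dlip2. RefSeq's gene table lists Dip2 and DIP2 among the synonyms of Dlip2, and also has a separate gene whose symbol is DIP2. Dlip2 was taken as the gene of the tagged protein.

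The authors deposited 4 lists of peaks that passed an irreproducible discovery rate (IDR) threshold, each with a longer ranked list of candidate peaks. Per the text deposited with the samples, 1 pair of lists came from each replicate's own alignments and the other pairs, called conservative and optimal here, came from the alignments of both replicates. All lists share 1 input that also made the deposited tracks of fold change over control, per that text, and was taken to be the control. The thresholded lists have 1 further input, whose content is not given in the sources used here. The aligner, the peak caller and their versions are not given in the sources used here. Each peak has a signal value given by the authors' peak caller, whose scaling is not stated in the deposited text. Each peak also has a scaled IDR score from the authors, and the ranked lists hold −log10 IDR values, as deposited. The lowest score in the thresholded lists was 830 or 831, which in the deposited −log10 values was an IDR of 0.00997 to 0.0100. The signal was used to describe, rank or filter peaks within a list and never between lists. The lists hold no read counts, so the depth of each library is unknown and no value here has an error from read counting. Intervals on shares are 95% Wilson intervals, or exact Clopper-Pearson intervals where named, and cover the number of peaks only. The control, signal tracks and alignments were not used here.

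The conservative list was the main set, because it was made from the alignments of both biological replicates and is the shorter of the lists made so. Of its 629 peaks, 417 (66.3%) overlapped a thresholded peak of replicate 1 and 505 (80.3%) one of replicate 2. Its background was all candidates of its ranked list that are not in the thresholded list. These include 21 candidates (10 on the arms) with an IDR score at or above the lowest score of the thresholded list. Peaks on the 7 chromosome arms (2L, 2R, 3L, 3R, 4, X and Y) were annotated with the Ensembl release 115 gene models and the RefSeq sequence of the same assembly, whose arm lengths held all of these peaks. Annotated transposable elements were not counted as genes. A summit within 500 bp of a transcript start was called a promoter summit, and the remaining summits were placed in the first matching class of 5' UTR, 3' UTR, coding exon, other exon, intron and intergenic. A gene was called bound when a summit of the main set lay within 500 bp of one of its starts. Coordinates are 1-based dm6 positions.

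Shares were compared with Fisher's exact test (two-sided), with Benjamini-Hochberg adjustment within each family. Overlap of the replicates (at least 1 bp) was compared with 10000 random placements of the other replicate's peaks on the same chromosome (one-sided permutation test). The side of the start was tested with an exact binomial test (two-sided), and signal inside and outside promoters with a permutation test of the difference in medians (100000 resamples, two-sided). A divergent promoter was a start of another gene on the opposite strand within 1000 bp upstream. There were 26 protein-coding gene lists, of which 25 had at least 5 members with a candidate summit within 500 bp, and 7 RNA classes were tested. Genes of miRNA precursors have the biotype of other non-coding RNAs in the annotation and were found by name. They are therefore counted in the long non-coding class as well. A total of 40 consensus motifs and all 6-mers (reverse complements joined) were sought within 100 bp of the summit on both strands and compared with 10 candidates per peak from outside the thresholded list, drawn with the same promoter status. Lists, motifs, tests and most alternatives were fixed before the data were examined. The named genes are those nearest to the 25 peaks of highest signal, up to 4 members by signal of each described list, Dlip2 and DIP2, and the genes nearest to the 5 strongest peaks of each replicate without an overlapping peak in the other.

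Alternatives were each replicate's own list (the other replicate left out), the optimal list, the upper part of the list by signal, promoter distances of 250 and 1000 bp, random positions or all annotated genes as background, assignment to the nearest start, motif windows of 50 and 250 bp, controls matched on GC content in bins of 5 percentage points, flanks 500 to 700 bp from the same summits, and another random draw. Merging overlapping peaks, matching on the exact number of G and C, restricting genes to those with divergent promoters, and assigning divergent promoters by the nearest start were chosen after seeing the data.

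The tests were checked on simulated data. With the CTCF core planted in 20% of windows drawn from candidates outside the thresholded list, the motif test found it in 20 of 20 draws and the 6-mer test found part of it in 19 of 20 draws. Without planting, 0 of 800 motif tests and 1 of 41600 6-mer tests passed. Simulated peaks and controls came from the same candidates. These draws therefore cannot show how many calls a difference in GC content between peaks and controls would give. The gene list test found a planted list in 20 of 20 draws and passed 1 of 500 tests without planting. The planted list was that of mitochondrial ribosomal proteins, with a larger share bound than the 20% in the data. How often the test would find a list at that share, or a shorter list, was not simulated. Genes were drawn singly there, whereas 128 of the 315 peaks with a gene start within 500 bp had more than 1 gene. The draws do not cover such shared peaks. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.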

Results

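Sites occupied by a Dip2-eGFP fusion protein were mapped by ChIP-seq in whole Drosophila embryos aged 0 to 18 hours. The series holds 1 group of 2 biological replicates, so the comparisons are between the replicates and between peaks in the authors' thresholded lists and candidates outside them. Replicate 1 had 550 thresholded peaks and replicate 2 had 742. The lists made from both replicates held 629 peaks (conservative) and 973 peaks (optimal), and 599 peaks were identical in both. The conservative list was drawn from 129448 candidates, and 611 of its peaks lay on the 7 chromosome arms, where they covered 0.149% of the sequence. The median peak was 364 bp long. Signal values are the authors' own and ran from 2.26 to 4828 in the conservative list, with a median of 127. In that list 16 peaks had a signal below the median of its candidates, 16.9. The lists hold no read counts, so the depth of each library is unknown.

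The strongest sites of each replicate were also peaks in the other. All 100 peaks of highest signal in replicate 1 overlapped a thresholded peak of replicate 2, and the same held for the 100 strongest peaks of replicate 2. Over the whole lists on the arms, 372 of 468 replicate 1 peaks (79.5%, Wilson interval 75.6% to 82.9%) overlapped a replicate 2 peak, and 383 of 734 replicate 2 peaks (52.2%, 48.6% to 55.8%) overlapped a replicate 1 peak. Random placement gave means of 0.364% and 0.231%, and none of the 10000 placements reached either observed share (one-sided permutation p = 1e-04 for each, the smallest these placements can give). Placements were uniform along each chromosome. The test therefore cannot tell binding of the fusion protein from other regions that give signal in both replicates. With each list divided into 4 bins of signal, the overlap was 100% in the highest bin of replicate 1 and 43.6% in its lowest, and 97.3% and 18.0% in replicate 2.

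Sites present in a single replicate's thresholded list were also examined. The 5 strongest of the 96 replicate 1 peaks without a replicate 2 peak lay nearest to the non-coding RNA entry FBtr0304242_df_nrg in an intron of MFS17, the pseudogene CR14578, rl (the ERK-type MAP kinase), Sox21a (an HMG-box transcription factor) and Gorab, with replicate 1 signals of 76.6 to 85.6. The strongest ranked 209 of the 468 peaks on the arms. The 5 strongest of the 351 replicate 2 peaks without a replicate 1 peak lay nearest to galectin, HmgD (an HMG-box chromatin protein, the site being in an intron of HmgZ), lbm (a tetraspanin), CG31145 and CG13323, with replicate 2 signals of 175 to 289, the strongest at rank 128 of 734. The Gorab site had a replicate 2 candidate with a scaled IDR score of 817, just under the lowest score of that thresholded list, 831. Scores of replicate 2 candidates were 390 at Sox21a, 237 at CR14578 and 10 at FBtr0304242_df_nrg, and rl had no candidate. Replicate 1 candidates scored 271 at lbm and 13 at HmgD, and galectin, CG31145 and CG13323 had none. Counting all candidates of the other replicate, 95.5% of replicate 1 peaks and 84.2% of replicate 2 peaks had an overlapping candidate. Replicate 1 had 101225 candidates on the arms and replicate 2 had 109992, so part of this overlap could arise by chance. Random placement was not run for candidates, and these shares have no background level. The number of peaks past a threshold also depends on read depth.

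The peak of highest signal (4828) lay on 2R at 23652185 to 23652648, in an intron of retn, which encodes an ARID transcription factor, 5139 bp upstream of the nearest start, that of Pde8, a cyclic nucleotide phosphodiesterase. The next (4552) lay on X at 1952906 to 1953391 in an intron of the nuclear receptor gene Hr4, nearest to the start of the pseudogene CR46447. The third (4111) was intergenic near CG13306 on 3L at 8748818 to 8749260, and the fourth (4053) lay in an intron of EcR, the ecdysone receptor gene, on 2R at 6150972 to 6151615, with tRNA:Asn-GTT-1-1 as the nearest start. The fifth (3778) lay in the 3' UTR of CG10357 on 3L at 3616344 to 3616775. Of the 25 strongest peaks, 11 were intergenic, 6 intronic, 3 in a 3' UTR, 1 in a coding exon and 4 in promoters, and all 25 overlapped thresholded peaks of both replicates. The promoter sites were those of CG7785, CG13689, Lap1 and Mtpalpha, the last encoding the alpha subunit of the mitochondrial trifunctional protein, with signals of 2574 to 3018. Further intronic sites lay in TfAP-2 (an AP-2 transcription factor, 3227), in Eaat2 (a glutamate transporter family gene, 2622) and in lncRNA:iab8 of the bithorax complex (3R at 16919059 to 16919452, 2911). The remaining 3' UTR sites were in raskol (2986) and CG10222 (2734), and the coding exon site was in klar, nearest to lncRNA:CR46002 (2654). Intergenic sites lay nearest to Jhbp1 (3722), CheB93b (3694), CG15615 (3421), CG5568 (3138), lncRNA:CR44282 (3030), CG44439 (2991), Atpalpha (the Na/K ATPase alpha subunit gene, 2733), CG12986 (2603), gol (a RING finger gene, 2501) and CG10232 (2464), besides CG13306.

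Over the whole conservative list, promoters were the most frequent location of summits. Promoters held 315 of 611 summits (51.6%, Wilson interval 47.6% to 55.5%) against 12.3% of 125886 candidates outside the thresholded list (odds ratio 7.60, Fisher's exact p = 3.27e-121, which is the test behind the exact p-values of shares that follow). The promoter share was 49.5% without replicate 1, 46.8% without replicate 2 and 48.2% in the optimal list, and 39.8% with promoters of 250 bp. Coding exons were nearly empty of summits, with 11 peaks (1.80%) against 18.7% of candidates (odds ratio 0.0796, adjusted exact p = 1.17e-38). Introns held 21.8% against 37.4% (adjusted exact p = 3.57e-16), intergenic sequence 20.9% against 26.7% (adjusted exact p = 0.00228) and 3' UTRs 1.47% against 3.25% (adjusted exact p = 0.0155). The shares of 5' UTRs (1.15% against 0.833%, adjusted exact p = 0.367) and other exons (1.31% against 0.845%, adjusted exact p = 0.216) did not pass. The intergenic and 3' UTR differences did not pass in replicate 1's list, that is without replicate 2 (adjusted exact p = 0.477 and 0.182), or in the upper part of the list by signal (adjusted exact p = 0.931 for each).

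**Figure D1:**
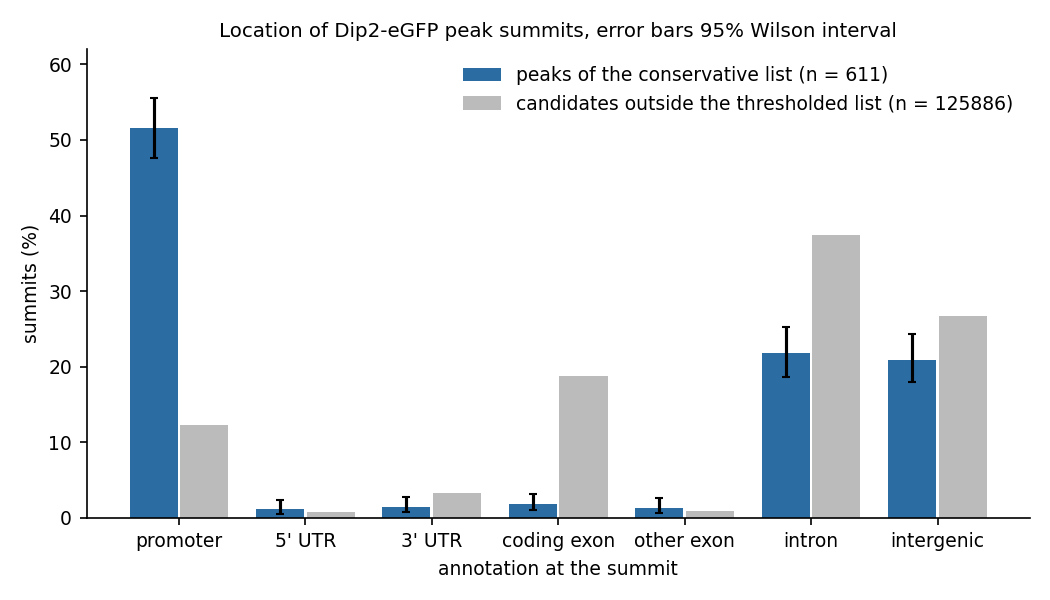
Share of summits (%) by annotation for the 611 conservative peaks on the chromosome arms (blue, error bars 95% Wilson interval) and the 125886 candidates outside the thresholded list (grey). Promoters held 51.6% of peaks and 12.3% of candidates, and coding exons 1.80% and 18.7%.

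Promoter summits lay upstream of the start. Of 315 promoter summits, 265 (84.1%, exact interval 79.6% to 88.0%) were upstream of the nearest transcript start (exact binomial p = 1.64e-36), with a median offset of -131 bp. Among promoter candidates outside the thresholded list, 40.2% were upstream and the median offset was 86 bp (odds ratio 7.89, Fisher's exact p = 9.83e-57, a comparison chosen after seeing the data). Bound genes often shared their upstream region with a gene on the other strand: 275 of 401 bound protein-coding genes (68.6%) had a divergent promoter, against 2961 of 8120 unbound genes with a candidate summit (36.5%, odds ratio 3.80, exact p = 5.99e-37). Without replicate 1 the shares were 62.3% and 39.9% (odds ratio 2.49, exact p = 8.28e-20). A single peak between divergent starts counted for both genes, and with each peak given to its nearest start alone the share was 55.6% against 37.4% (odds ratio 2.10, exact p = 1.61e-09). A summit between divergent starts is also upstream of its nearest start by definition. The upstream share and the divergent share are therefore linked, and the upstream share of promoters without a divergent start is not given here.

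Median signal was 121 at promoter peaks and 145 elsewhere, a difference of -23.9 (permutation p = 0.0305, 100000 resamples, two-sided). This difference depended on the list and on how promoters and peaks were defined: without replicate 1 it was 2.59 (permutation p = 0.557), without replicate 2 it was -12.0 (permutation p = 0.136) and in the optimal list it was 7.79 (permutation p = 0.0705), while in the upper part of the conservative list it was -246 (permutation p = 1.3e-04). It was -13.8 with promoters of 250 bp (permutation p = 0.227), -54.3 with promoters of 1000 bp (permutation p = 9e-05) and -41.1 with overlapping peaks merged (permutation p = 0.00147), the last chosen after seeing the data.

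Among gene lists, genes for mitochondrial ribosomal proteins were bound more often than other genes. Of 35 members with a candidate summit, 7 were bound (20%) against 4.64% of other protein-coding genes (odds ratio 5.13, adjusted exact p = 0.0259), among them mRpL41 (signal 440, summit offset -118 bp from the start), mRpS23 (358), mRpS10 (326) and mRpL23 (232). All 7 peaks lay within 500 bp of a start of another gene too. Heat shock genes had 3 of 7 members bound against 4.67% (odds ratio 15.3, adjusted exact p = 0.0393), namely Hsp27 (a small heat shock protein, signal 171), Hsc70-5 (a mitochondrial chaperone, 95.3) and Hsc70-4 (a constitutive cytosolic chaperone, 72.0). Neither list passed with either replicate's own list. Of the mitochondrial ribosomal protein genes, 7 of 41 (17.1%) were bound without replicate 1 (adjusted exact p = 0.0678), 4 of 34 (11.8%) without replicate 2 (adjusted exact p = 0.706) and 3 of 35 (8.57%) with each peak given to its nearest start (adjusted exact p = 0.627). Of the heat shock genes, 2 of 11 (18.2%, odds ratio 4.52, adjusted exact p = 0.382) were bound without replicate 1 and 1 of 6 (16.7%, odds ratio 4.78, adjusted exact p = 0.875) without replicate 2. Over all alternatives the adjusted exact p was 0.0529 to 0.706 for the former list and 0.0270 to 0.931 for the latter, which passed with promoters of 250 bp and with each peak given to its nearest start.

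Genes for insulator and architectural proteins had 3 of 13 members bound (odds ratio 6.11, exact p = 0.0208, adjusted exact p = 0.173), namely Chro (signal 355), pzg (115) and row (71.5). Cytoplasmic ribosomal protein genes had 4 of 53 bound (adjusted exact p = 0.876), namely RpL32 (138), RpS4 (116), RpS20 (102) and RpL34b (76.6); RpL32 was also the 1 bound member among 6 common reference genes (adjusted exact p = 0.867). Translation initiation factors had 3 of 27 bound (eIF6, eIF3c and eIF5B, adjusted exact p = 0.659), Polycomb and Trithorax group genes 2 of 19 (ph-p and brm, adjusted exact p = 0.867), replication and cell cycle genes 2 of 22 (Dp and RnrS, adjusted exact p = 0.867) and the MADF-BESS family 2 of 13 (brwl and CG5953, adjusted exact p = 0.659). The pair-rule and segment polarity list had 1 bound member of 17, pan, with a signal of 967, and the neural list 1 of 23, elav, with 199 (adjusted exact p = 1 for each). In 14 lists with 176 distinct genes none was bound: proteasome subunits, spliceosome proteins, Hox genes, maternal and gap genes, dorsoventral patterning genes, Toll and Imd pathway genes, antimicrobial peptides, zygotic cellularisation and sex determination genes, and the markers of glia, muscle, germline, midgut and fat body, epidermis and trachea, and haemocytes. Their tests did not pass (adjusted exact p = 1 for each). They could not have shown depletion: 0 of 27 proteasome genes, the longest of these lists, against 4.72% of other genes gave an unadjusted exact p of 0.637. Replication-dependent histones were not tested because 1 gene had a candidate summit.

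Protein-coding genes were bound more often than the pool of all other genes, most of which were long non-coding RNA genes. Of 8521 with a candidate summit, 401 were bound (4.71%) against 1.63% of other genes (odds ratio 2.99, adjusted exact p = 1.76e-12). Long non-coding RNA genes, a class that here includes the miRNA genes, were bound less often. Of 2021 genes 30 were bound (1.48%) against 4.63% of all others (odds ratio 0.310, adjusted exact p = 4.01e-12). Those others were mostly protein-coding, so this and the preceding comparison are largely the same contrast. Transfer RNA genes had 5 of 100 bound, at 4 peaks (adjusted exact p = 0.604), and small nuclear RNA genes 2 of 19 (adjusted exact p = 0.249). None of 112 pseudogenes was bound (adjusted exact p = 0.0577). Of 84 snoRNA genes (adjusted exact p = 0.309) and 134 miRNA genes (adjusted exact p = 0.0797), 1 each was bound.

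AGRKGGC is the core of the motif of CTCF, a zinc finger insulator protein. It occurred within 100 bp of the summit in 199 of 611 peaks (32.6%) against 9.20% of control candidates (odds ratio 4.77, adjusted exact p = 4.70e-49). The odds ratio was 4.22 without replicate 1, 5.77 without replicate 2 and 3.41 in the optimal list, and ran from 2.92 (windows of 250 bp) to 10.7 (upper part of the list by signal) over all alternatives. Among windows of 250 bp either side of the summit that held a match, the match centre lay within 25 bp of the summit in 117 of 264 peaks (44.3%) and in 12.9% of control windows with a match (Fisher's exact p = 4.21e-28). Of the 25 strongest peaks, 23 held the core, with the nearest match centred at most 65 bp from the summit; the sites near CheB93b and in CG10222 held none. GGCGCY, entered as the Brinker motif, occurred in 28.2% against 12.2% (odds ratio 2.82, adjusted exact p = 2.31e-22), and 134 of these 172 windows also held AGRKGGC.

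**Figure D2:**
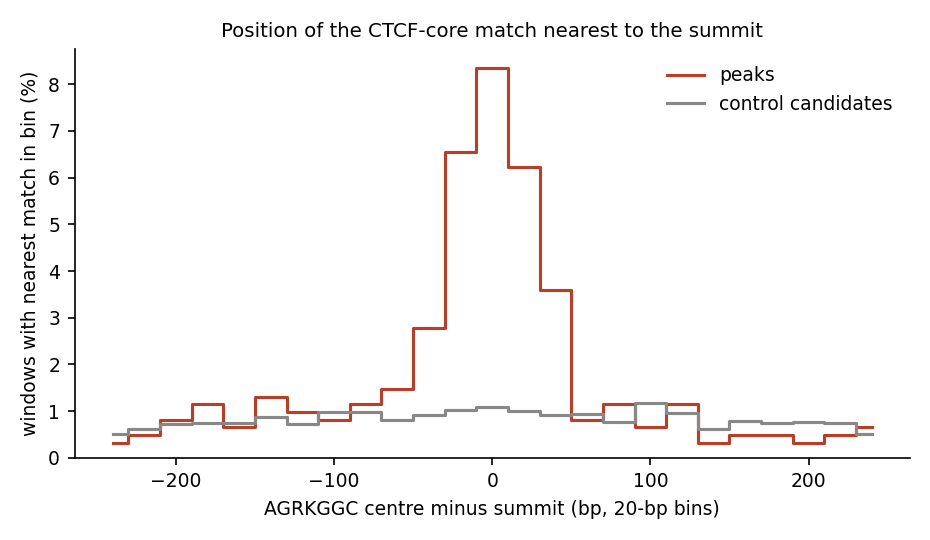
Position of the AGRKGGC match nearest to the summit (x axis, bp, in bins of 20 bp) as a share of all windows (y axis, %), for 611 conservative peaks (red) and their control candidates (grey). The central bin held 8.35% of peaks and 1.08% of controls.

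The CTCF core was most frequent in peaks of high signal, in a comparison of 4 signal bins chosen after seeing the data. It was present in 115 of 153 peaks of the highest bin (75.2%, Wilson interval 67.8% to 81.3%), in 28.8% and 11.8% of the next bins and in 22 of 152 peaks of the lowest bin (14.5%, 9.76% to 20.9%; highest against lowest, odds ratio 17.9, adjusted exact p = 4.71e-27). Promoter summits made up 37.9% of the highest bin, 58.8% and 56.2% of the next and 53.3% of the lowest (highest against lowest, adjusted exact p = 0.0185). The shares with TATAAA were 30.7%, 41.2%, 41.8% and 34.2% from the highest bin to the lowest, and highest against lowest did not pass (adjusted exact p = 0.610). Outside promoters the core occurred in 44.6% of peaks against 9.70% of controls (odds ratio 7.50), and in promoters in 21.3% against 8.73% (odds ratio 2.82).

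**Figure D3:**
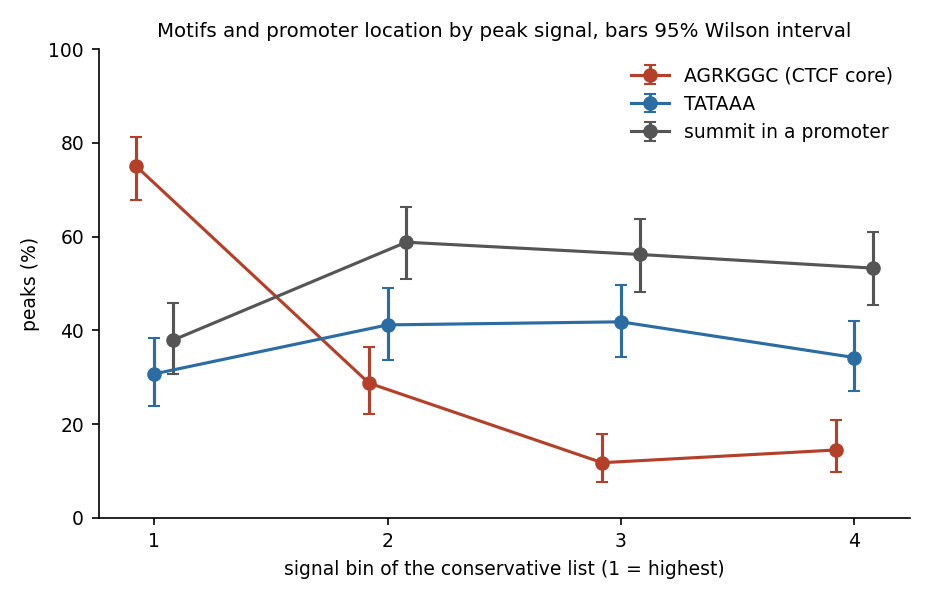
Share of conservative peaks (y axis, %) with AGRKGGC (red) or TATAAA (blue) within 100 bp of the summit, and with the summit in a promoter (grey), by signal bin (x axis, 1 is the highest of 4); bars are 95% Wilson intervals. The CTCF core was in 75.2% of the highest bin and 14.5% of the lowest. The promoter share was 37.9% in the highest bin, 58.8% and 56.2% in the next and 53.3% in the lowest.

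Peak windows were also rich in A and T, with a median GC content of 36.3% against 46.8% in controls. In the flanks of the same summits the median was 43.3%. TATAAA occurred in 37.0% against 15.2% (odds ratio 3.27, adjusted exact p = 5.58e-34), and TTTATK, entered as the Caudal motif, in 60.4% against 35.5% (odds ratio 2.77, adjusted exact p = 1.89e-31). The DRE sequence TATCGATA of DREF and BEAF-32 occurred in 2.78% against 0.671% (odds ratio 4.24, adjusted exact p = 5.98e-05), CGATA in 30.9% against 21.5% (adjusted exact p = 1.89e-06) and the Su(Hw) core in 2.78% against 0.982% (adjusted exact p = 0.00133). The DRE odds ratio was 10.3 without replicate 2 (3.21% against 0.321%) and 4.51 without replicate 1. In all, 10 of the 40 motifs were more frequent in peaks and 7 less frequent. Of 2080 6-mers, 426 were more frequent and 719 less frequent, led by ATTTTA in 49.4% of peaks against 19.6% (adjusted exact p = 3.33e-51). Against controls matched on GC content 5 motifs were more and 2 less frequent. The odds ratio of AGRKGGC was 8.22, that of GGCGCY 6.62, that of CGATA 1.47 and that of TATAAA 1.33. The remaining more frequent motif had not passed in the main comparison. DRE (odds ratio 2.13, adjusted exact p = 0.0576) and the Su(Hw) core (odds ratio 1.80, adjusted exact p = 0.163) did not pass. Nor did TTTATK (odds ratio 1.08, adjusted exact p = 0.634). The leading 6-mer was then GCGCCA, in 28.2% of peaks against 5.67% (adjusted exact p = 1.00e-55), with 101 6-mers more and 52 less frequent.

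Across chromosomes, 3R held fewer peaks than its candidates, with 123 of 629 (19.6%) against 25.4% (odds ratio 0.715, adjusted exact p = 0.00532). X held 21.0% against 17.1% (odds ratio 1.29, adjusted exact p = 0.0502), which passed without replicate 1 (odds ratio 1.44, adjusted exact p = 6.03e-04) and against random positions (odds ratio 1.33, adjusted exact p = 0.0183) but not without replicate 2 (16.7% against 15.7%, odds ratio 1.08, adjusted exact p = 0.628) or in the optimal list (odds ratio 1.15, adjusted exact p = 0.204). Sequence outside the arms held 18 peaks (2.86%) against 2.28% (adjusted exact p = 0.461), but 82 of 550 peaks in replicate 1's own list, that is without replicate 2 (14.9% against 2.66%, adjusted exact p = 8.93e-35). In the optimal list, also made from both replicates, it held 63 of 973 (6.47% against 2.52%, odds ratio 2.68, adjusted exact p = 3.74e-10), and without replicate 1 it held 8 of 742 (1.08% against 1.13%, adjusted exact p = 1). The 3R difference did not pass in the upper part of the list by signal (adjusted exact p = 0.159) or against random positions (adjusted exact p = 0.145).

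Summits in repeat-masked bases made up 137 of 611 (22.4%) against 13.4% of candidates (odds ratio 1.87, exact p = 1.35e-09). None lay in an annotated transposable element (0 of 611, Wilson upper bound 0.625%), against 1.67% of candidates (exact p = 8.24e-05). The excess of masked summits was not found in the upper part of the list (odds ratio 1.26, exact p = 0.135) or against random positions (odds ratio 1.14, exact p = 0.174). In the 4 signal bins, chosen after seeing the data, masked summits made up 7.19% of the highest bin, 25.5% and 32.7% of the next and 24.3% of the lowest (highest against lowest, odds ratio 0.241, adjusted exact p = 1.05e-04).

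The gene of the tagged protein was not a binding site in any thresholded list. Dlip2 (FBgn0040466, 3R at 4644649 to 4645655, minus strand) had 3 candidate summits within 2000 bp in the list behind the conservative set, the strongest with a signal of 37.7 and rank 7215. The separate gene DIP2 (FBgn0024806, 3L at 250229 to 257954) had 1 candidate in that list, with a signal of 40.2, and no thresholded peak.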

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

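The comparison of signal percentiles in this part was chosen after the result was seen. Some candidates had a scaled IDR score at or above the lowest score of a thresholded list and were yet absent from that list. This concerned 147 peaks for replicate 1, 26 for replicate 2, 21 for the conservative list and 125 for the optimal list. The comparisons of the report count them among the candidates outside the thresholded list, not as peaks. In the conservative list, 10 of the 21 were on the arms; the genes named here were chosen after their values were seen. The strongest lay 165 bp upstream of the nearest start of InR, the insulin receptor gene (3R at 21619297 to 21619703, signal 1994, which would rank 35 in the list), followed by sites at the promoter of CG1943 (1004) and in an intron of ush (611, nearest start cbt). Most of those of replicate 1 lay on unplaced sequence (61) or Y scaffolds (30).

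Low signal does not account for the absences, since the median percentile of the missing peaks among all peaks past the score was 40.3. Of the 319 absences, counted once per list so that a site can count several times, 0% overlapped a peak kept in any of the 4 thresholded lists, although the InR site passed the score in each. This is consistent with removal of a fixed set of regions from all thresholded lists, such as the further input named in the deposited text could hold, but that input was not used here. Whether these sites are bound stays open, and no biological explanation was tested.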

How the results depend on the processing

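The exact matching on G and C, the restriction to divergent promoters, merged peaks and divergent promoters by nearest start were tests chosen after the results were seen. The replicate overlap (74.1% to 95.3% of replicate 1 peaks and 48.0% to 61.0% of replicate 2 peaks), the promoter share (odds ratios 5.94 to 9.65), the upstream share (78.0% to 85.4%) and divergent promoters (odds ratios 2.10 to 5.05) kept their direction and side of the threshold under all alternatives run for them. Apart from the values given for each below, the numbers past the threshold were 16 to 24 motifs (17 in the main analysis), 830 to 1243 6-mers (1145) and 2 to 3 RNA classes (2). With each replicate left out in turn, the location classes past the threshold numbered 3 to 5 (5 in the main analysis). The chromosomes, with sequence outside the arms counted among them, numbered 2 to 3 (1), and the gene lists 0 (2). The promoter signal difference was -12.0 to 2.59 (-23.9). In the optimal list, 3R, sequence outside the arms and 0 gene lists passed, and the signal difference was 7.79. In the upper part of the list by signal, 3 location classes, 0 chromosomes and 0 gene lists passed, and the odds ratio of masked summits was 1.26; the set there is smaller. Against random positions 2 chromosomes passed and the odds ratio of masked summits was 1.14. With all annotated genes as background 0 gene lists and 5 RNA classes passed. With promoters of 250 bp 1 gene list passed and the signal difference was -13.8, and with 1000 bp 0 lists passed. With the nearest start 1 list passed (heat shock genes), and among divergent promoters 0 (odds ratio of mitochondrial ribosomal proteins 4.04 against 5.13, heat shock genes not tested with 4 members). The cause was not tested for these. Against flanks of the same summits 9 motifs and 660 6-mers passed, against controls matched on GC content 7 and 153, and on the exact number of G and C 8 and 149. Among the 17 motifs past the threshold in the main analysis, the odds ratio crossed 1 under these 2 matchings for Zeste (1.09 and 1.09), homeodomain (0.881 and 0.908), GATA (0.980 and 0.918), A tract (0.794 and 0.805), GC box (1.15 and 1.28) and G run (1.28 and 1.22), none past the threshold. Of the named classes, lists and motifs, 220 values kept their call, 53 lost it, 9 gained one and 12 reversed. Read depth is unknown, so its effect on the number of peaks cannot be assessed. No paired analysis was possible because the series holds 1 group.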

Other observations

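The longer form of the CTCF-type core and the exact GC matching in this part were chosen after the data were seen. In 114 of the 153 peaks of the highest of 4 signal bins a core match could be aligned, and the bases after AGRKGGC were G in 91.2% and C in 78.1%. AGRKGGCGC occurred in 22.7% of conservative peak windows against 0.606% of controls. Of its 2958 matches on the 7 arms, 171 (5.78%) lay in a conservative peak, whereas peaks cover 0.149% of the sequence, and 1339 (45.3%) lay in any candidate. These shares are not independent of the peaks from which the longer form was read.

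The CTCF-type core in peak windows does not follow from the GC content of the windows, since the odds ratio against GC-matched controls was 8.22 (95% interval 6.71 to 10.1). Repeat-derived sequence and the general signal of promoters are argued against by odds ratios of 5.81 without repeat-masked summits and 7.50 among peaks outside promoters. The core was in 11.8% and 14.5% of peaks in the lower signal bins, against 9.20% of all controls. A match within 250 bp was present in 264 of 611 peaks. Among peaks and controls with such a match, the odds ratio for a match within 25 bp of the summit was 5.37 (4.0 to 7.20). This does not cover peaks without a match, but is the pattern predicted if summits are placed on this motif where it occurs. Whether Dip2-eGFP may bind it itself, be held there by another protein, or whether the sites attract signal in any GFP precipitation stays open, because embryos without the tag were not analysed here. The design has 1 group and no biological explanation was tested.

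The TATAAA excess shrank from an odds ratio of 3.27 to 1.33 (95% interval 1.12 to 1.59) against GC-matched controls and was 1.35 (1.13 to 1.60) with the exact number of G and C. Base composition may thus account for much of the excess but, as the interval stays above 1, not for all of it. The main controls were matched on promoter status but not on finer location. Coding exons, for example, held 1.80% of peaks and 18.7% of candidates, and promoter summits differed in their side of the start. Whether such differences in location account for the GC content was not tested. What lowers the GC content of the peaks stays open.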
